A study of Homo sapiens with 4 samples.

How the data were processed

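RNA of AGS and MKN1 gastric cancer cells transfected with siScramble or siHOXB9 was sequenced as 4 libraries, 1 per line and siRNA. Per the labels, RNA was purified by binding to poly-T beads, fragmented by heat, reverse transcribed with random primers and made into Illumina libraries. The deposited table holds 57815 rows by gene symbol and 1 column of FPKM values per library, computed by the authors. The values were never negative and not whole, and their sums differed between libraries (831098 for AGS siScramble, 777152 for AGS siHOXB9, 784213 for MKN1 siScramble and 826111 for MKN1 siHOXB9), so the columns were not scaled to a common total. The genome builds were GRCh38 and hg38, per the submitters' processing notes. The aligner, the counting tool, their versions and the annotation release are not given in the sources used here. The labels describe no step that keeps the strand of the RNA, so reads from overlapping genes on opposite strands may not have been separable.

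The table names genes by symbol alone. Of its symbols 291 were repeated over 2348 rows, most of them small RNAs, and 29 looked like dates. Each row was kept as its own feature. Symbols were joined to GENCODE release 29 for position, biotype, transcripts and shared exons. Of 14827 rows with at least 1 FPKM in any library, 13178 had a gene in that release and 12277 were protein-coding. There were 480 rows at 0 in a library and at 5 FPKM or more in another. Values listed at 0 were given as such and without a fold.

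The files give no counts. Depth was estimated from genes with a single transcript and low values, where FPKM falls on multiples of the value of 1 fragment. With transcript lengths shortened by 260 bases, 57.5% to 60.4% of these values lay within 0.05 of a whole number of fragments, and the depths were about 13020000, 12520000, 11510000 and 10640000 fragments for AGS siScramble, AGS siHOXB9, MKN1 siScramble and MKN1 siHOXB9. The siHOXB9 depth was thus 96.1% of the control in AGS and 92.5% in MKN1. A fragment in a transcript of 2 kb corresponds to 0.0384 to 0.0470 FPKM. Fragment numbers derived from these depths are estimates.

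Changes within a line were log2((siHOXB9 FPKM + 1)/(siScramble FPKM + 1)). With 1 library per group no test was made within a line. A gene was counted as higher or lower when this change was at least 1 in size, among genes with at least 1 FPKM in either library of the line. For both lines the counts in the same and in opposite directions were set beside those expected of independent lists, and Pearson's r and Spearman's rho were computed across genes. Over both lines, limma was fitted to log2(FPKM + 1) with terms for line and siRNA, an intensity trend in the variance and no robust option, among 13758 genes with at least 1 FPKM in at least 2 libraries. Tests were two-sided, with Benjamini-Hochberg adjustment at 0.05. The fit has 1 residual degree of freedom, which is the disagreement of the lines. The difference between MKN1 and AGS came from the same fit, with a size of at least 1 on the log2 scale.

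In total 44 gene lists were fixed, with 1052 members that have a row and 14 names without one, covering developmental regulators, cell cycle, stress, signalling, metabolism, epithelial identity and markers of other cell types. In each line the median change of a list was placed among 10000 random lists of the same size, matched on mean expression in 20 bins, and a list stood apart at or under percentile 2.5 or at or over 97.5. Over both lines the lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. The genes named were HOXB9, the 10 largest differences in each direction per line and over both lines among protein-coding genes with at least 5 FPKM in a library of the line, ranked over both lines by the smaller of the 2 changes, the 10 largest differences in each direction between the lines, up to 4 members of a list with the largest change, and all measured members of the lists of interest. Comparisons, size rule, lists, named genes and most alternatives were fixed before the data were examined.

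The alternatives were a pseudocount of 0.1 FPKM, no filter or a filter of 5 FPKM, rescaling each library to a common total, centring on the median gene, quantile normalization, a size rule of 1.5-fold, variance estimation without trend or with the robust option, a fit without the line as a block, unmatched random lists and means in place of medians. Restricting the data to protein-coding genes with a single row and no shared exon, and centring for the gene lists, were added after seeing the data. The analysis was tested on simulated data. The limma fit recovered 161 of 200 genes changed by 2 on the log2 scale and 0 of 200 changed by 1. Of 100 random lists without a shift, 7 stood apart, and all 100 lists of 25 genes shifted by 0.5 did. The 3' UTR words described in the closing observations were ranked over all words of 7 bases in 7631 genes. The change, limited to 2 in size, was regressed on the presence of the word, given mean expression and the length and GC content of the 3' UTR, each of these last with its square. Words planted in permuted AGS changes, with their carriers lowered by 0.5, ranked first. The first word found had smaller effects (-0.09 in AGS and -0.21 in MKN1), and recovery at that size was not simulated. The tools were R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. All 4 value columns were used. Small RNAs, pseudogenes and clone-named genes were counted and, with 1 stated exception, not named, because a library of polyadenylated RNA measures many of them poorly.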

Results

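The data are 4 RNA-seq libraries from AGS and MKN1, human cell lines derived from gastric carcinomas. Cells of each line were transfected, with a lipid reagent, with a small interfering RNA (siRNA) against HOXB9 (siHOXB9) or with a scrambled control siRNA (siScramble), and 1 library of polyadenylated RNA was sequenced per line and siRNA. HOXB9 is a homeobox transcription factor of the HOXB cluster. The labels give the purpose of the study as the search for potential HOXB9 target genes in gastric cancer cells. There were no replicates within a line, so every value within a line stands on 1 library per group, and the 2 lines served as the only repeat of the knockdown. The depth recovered from low values was about 13020000 fragments for AGS siScramble, 12520000 for AGS siHOXB9, 11510000 for MKN1 siScramble and 10640000 for MKN1 siHOXB9, to the nearest 10000. At 1 FPKM (fragments per kilobase of gene, scaled to sequencing depth) or more, these libraries held 12770, 12745, 12537 and 12674 genes in the same order. Across genes, Pearson's r of the log2 values was 0.981 between the AGS libraries and 0.982 between the MKN1 libraries, and 0.759 to 0.774 between libraries of different lines. Genes are not independent replicates in these correlations.

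HOXB9 transcript was lower in the siHOXB9 library of both lines. In AGS it was 16.4 FPKM with siScramble and 4.44 FPKM with siHOXB9, which is 27.0% of the control. In MKN1, where the control level was lower, it was 1.14 FPKM with siScramble and 0.218 FPKM with siHOXB9, which is 19.1% of the control. On the log2 scale with 1 FPKM added, the changes were -1.68 in AGS and -0.81 in MKN1. HOXB9 (ENSG00000170689.9) lies on the reverse strand of chromosome 17 from 48621159 to 48626356 in GRCh38 and has 1 annotated transcript with 2 exons and 2581 bases. At the recovered depths these values were estimated to come from 497 fragments against 129 in AGS and 30.4 against 5.38 in MKN1, so the MKN1 percentage rests on few fragments. Over both lines the limma estimate was -1.25 (SE 0.268, 1 library per group in each of 2 lines), with an unadjusted p of 0.00219 and an adjusted p of 0.355 over all genes tested. HOXB9 passed the size rule of a 2-fold difference in AGS, not in MKN1, where with a pseudocount of 0.1 FPKM the change was -1.96 and passed it. Over both lines it did not pass the threshold across all genes.

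**Figure D1:**
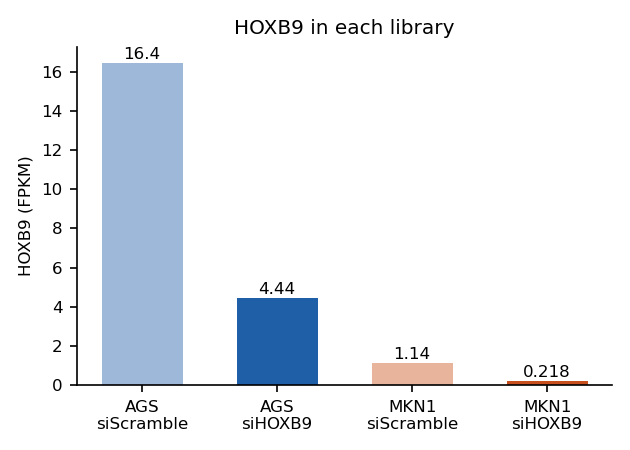
HOXB9 level in each of the 4 libraries, in FPKM, for AGS and MKN1 with siScramble or siHOXB9, with 1 library per bar. The siHOXB9 bar reads 4.44 FPKM against 16.4 FPKM in AGS and 0.218 FPKM against 1.14 FPKM in MKN1.

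The first comparison asked which genes differed between siHOXB9 and siScramble in AGS. Cell cycle genes and genes of the integrated stress response were lower with siHOXB9, and interferon response genes and mitochondrially encoded genes were higher. All 53 measured G2M phase genes were lower, with a median log2 change of -0.78, and 13 of them passed the size rule of a 2-fold difference. Among them were BIRC5 (survivin, 50.7 FPKM against 19.1, log2 -1.36), CDC20, which activates the anaphase-promoting complex (208 against 85.8, log2 -1.27), and PLK1, a mitotic kinase (81.1 against 34.0, log2 -1.23). Of 41 S phase genes, 40 were lower (median -0.54), including RRM1, the large subunit of ribonucleotide reductase (57.9 FPKM against 25.3), and TYMS, thymidylate synthase (108 FPKM against 51.3).

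Of 26 integrated stress response genes, which are largely driven by the transcription factor ATF4, 24 were lower in AGS with siHOXB9 (median -0.73) and 8 passed the size rule. CHAC1, a glutathione-degrading enzyme, was at 54.9 FPKM against 14.9 (log2 -1.82), ASNS, asparagine synthetase, at 76.0 against 23.1 (log2 -1.68), DDIT4, an inhibitor of mTORC1 signalling, at 178 against 60.9 (log2 -1.53), and PSPH, a serine synthesis enzyme, at 39.2 against 13.6 (log2 -1.46). All 37 interferon response genes were higher (median 0.67), and 7 passed the size rule. CXCL10, an interferon-induced chemokine, was at 1.51 FPKM against 5.80 (log2 1.44), and the antiviral gene IFIT1 at 14.6 against 36.8 (log2 1.28). IFI44L and IFIT3 followed at log2 1.27 and 1.12. All 13 mitochondrially encoded genes were higher (median 0.78), for example MT-ND5, a complex I subunit, with 131 FPKM against 252. Mitochondrial transcripts made up 0.988% of the summed FPKM in AGS siScramble and 1.79% in AGS siHOXB9.

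Smaller shifts concerned several further lists in AGS. Glycolysis genes had a median of -0.37, with HK2, a hexokinase, at 20.3 FPKM against 12.1 (log2 -0.71) and LDHA, lactate dehydrogenase A, at 491 against 304 (log2 -0.69). Genes of the MAPK feedback list had a median of -0.33, with ETV4, an ETS transcription factor, at 58.3 FPKM against 23.5. DNA damage response genes (median -0.25, with RAD51C at log2 -1.34), NRF2 targets (-0.24), MYC targets (-0.23) and cytosolic ribosomal protein genes (-0.21) were also low. High medians were found for 6 genes of MHC class I antigen presentation (0.37, with B2M, the light chain of MHC class I, at 1668 FPKM against 2255 and HLA-B, in the MHC region, at 1.55 against 2.61), autophagy and lysosome genes (0.25), proteases and their inhibitors (0.23), extracellular matrix (0.21), intestinal epithelial markers (0.17) and epithelial junction genes (0.13). In the protease list the member that differed most went the other way: MMP1, interstitial collagenase, was at 185 FPKM against 49.2 (log2 -1.89). HMOX1, heme oxygenase 1, likewise stood against the NRF2 list, with 47.8 FPKM against 148 (log2 1.62).

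Among single genes in AGS, the 10 protein-coding genes with the largest positive differences, of those with at least 5 FPKM in either library, were ZBTB43 (2.49 FPKM against 34.4, log2 3.34), CYP27B1, SVIL, TMEM164, METAP1D, TRANK1, ZHX3, SPINK1, HSD3B1 and NPPB. CYP27B1 makes the active form of vitamin D (0.418 FPKM against 9.95), SPINK1 is a trypsin inhibitor (5.13 against 23.6), HSD3B1 is a steroid dehydrogenase (log2 1.76), and NPPB encodes B-type natriuretic peptide (1.06 against 5.96). The 10 with the largest negative differences were USP41, CHURC1-FNTB, VARS, SYTL4, CMTM1, BAG6, LY6D, LCOR, TSGA10 and ARHGAP33. USP41 was at 88.6 FPKM with siScramble and was listed at 0 with siHOXB9 and in both MKN1 libraries. VARS, valyl-tRNA synthetase, was at 30.3 FPKM against 1.76 (log2 -3.50), and LCOR, a nuclear receptor corepressor, at 16.5 against 3.23 (log2 -2.04). CYP27B1, SVIL, METAP1D, ZHX3, CHURC1-FNTB, SYTL4, CMTM1, BAG6, LY6D, TSGA10 and ARHGAP33 share exon sequence with another annotated gene, and VARS and BAG6 lie in the MHC region of chromosome 6, where 26 of 176 protein-coding genes reached 1 FPKM in any library.

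By the size rule, 223 genes were higher and 293 lower in AGS with siHOXB9, among 13252 genes with at least 1 FPKM in either library, so 43.2% of the differences were upward. With each library rescaled to the same total the split was 314 higher and 263 lower (54.4% upward), and after centring on the median gene it was 271 and 243 (52.7%). Of 38 fixed gene lists with at least 5 measured members, 17 stood apart from matched random lists in AGS, 8 on the high side and 9 on the low side, where 1.9 would be expected by chance. The directions of these 17 lists held after centring, which shifts every AGS change by 0.067 in size and so could turn none of them. The remaining 21 lists lay within the central 95% of random lists, among them p53 targets (median -0.14), hypoxia (-0.14), cholesterol synthesis (-0.12) and WNT targets (-0.14). With 1 library per group these percentiles describe the libraries and carry no replicate error. By the mean in place of the median, the MHC class I (percentile 95.3), NRF2 (22.7) and protease (72.2, mean -0.02) lists no longer stood apart, and intestinal markers did not with unmatched random lists. NRF2 targets and intestinal markers no longer stood apart with a filter of 5 FPKM, which left 4 MHC class I genes, and the MYC, glycolysis, DNA damage and extracellular matrix lists no longer did among protein-coding genes that share no exon, a selection chosen after seeing the data. Other lists stood apart under an alternative alone: unfolded protein response (percentile 98.6) and gastric markers (97.6) with the filter of 5 FPKM, stem cell genes by the mean (97.9), and WNT targets (0.44) and NF-kappaB genes (99.8) among genes that share no exon.

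**Figure D2:**
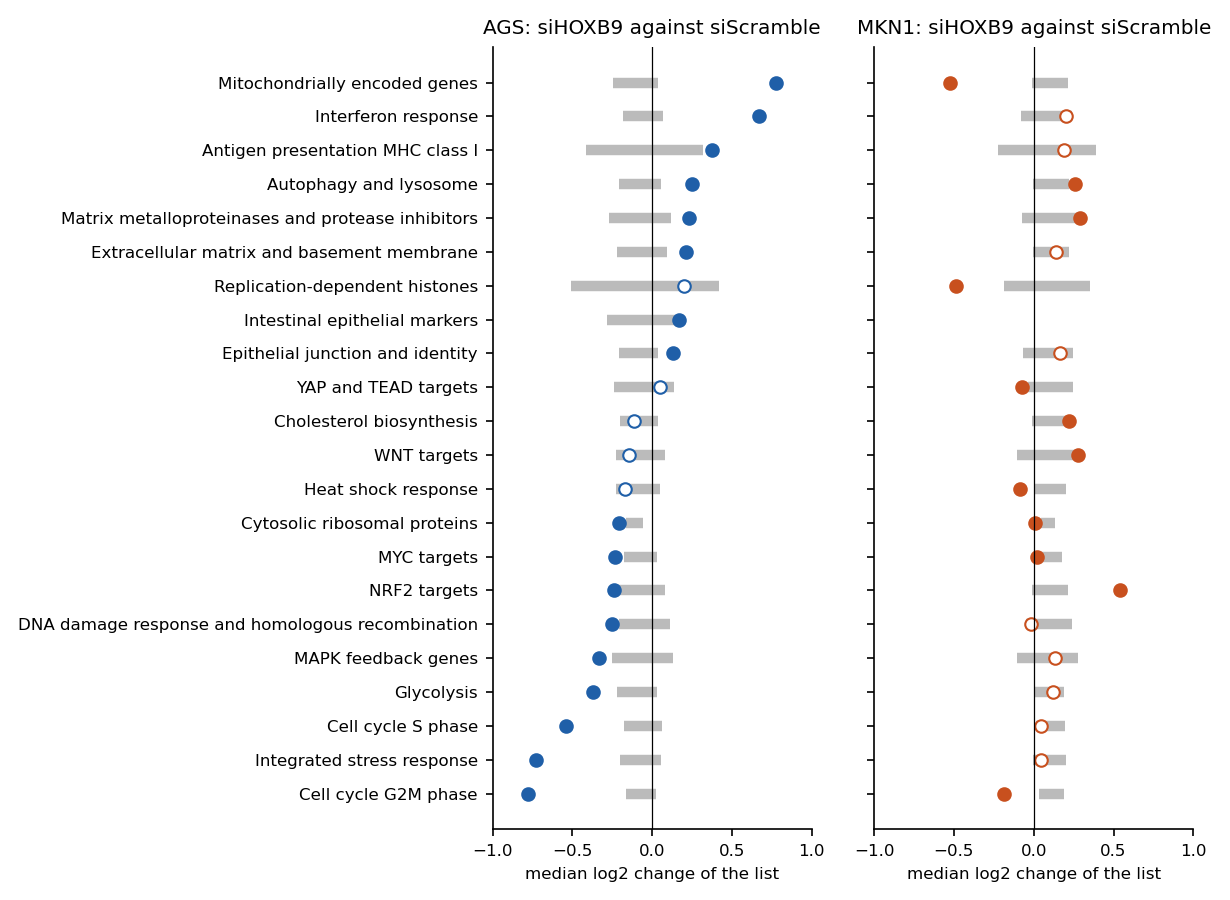
Median log2 change (siHOXB9 against siScramble, 1 FPKM added) of the fixed gene lists in AGS and MKN1, with the central 95% of 10000 random lists matched on expression. G2M genes lie at -0.78 in AGS and -0.19 in MKN1, interferon genes at 0.67 and 0.21, and mitochondrially encoded genes at 0.78 and -0.52.

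**Figure D3:**
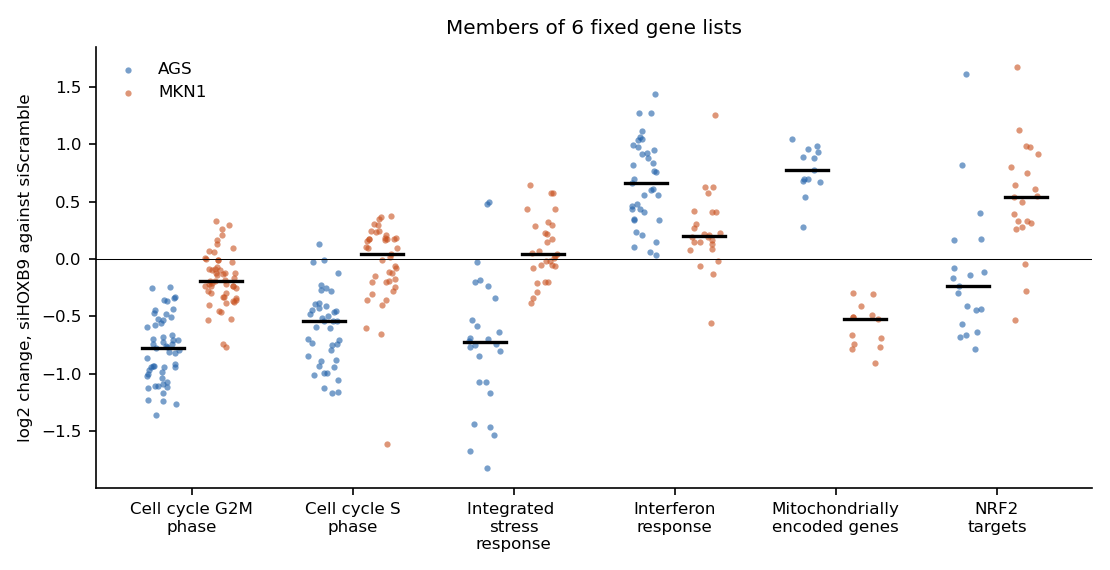
Log2 change of every measured member of selected fixed lists in each line, 1 point per gene, from 1 library per group. In AGS all 53 G2M genes lie below 0 and all 37 interferon genes above 0, and in MKN1 43 of 53 G2M genes lie below 0 and 20 of 24 interferon genes above 0.

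The same question was asked in MKN1. Here NRF2 targets, the genes of the oxidative stress response, were higher with siHOXB9, and mitochondrially encoded genes, replication-dependent histone genes and G2M genes were lower. Of 21 measured NRF2 targets, 18 were higher (median 0.54), including HMOX1 (15.1 FPKM against 50.2, log2 1.67) and the aldo-keto reductase genes AKR1C1 (17.6 against 39.5, log2 1.12), AKR1C2 (7.45 against 15.7) and AKR1C3 (55.8 against 111). All 13 mitochondrially encoded genes were lower (median -0.52), with MT-ND6, a complex I subunit, at 82.3 FPKM against 43.4, and mitochondrial transcripts made up 0.687% of the summed FPKM with siScramble and 0.470% with siHOXB9. Of 53 G2M genes 43 were lower, by a smaller median (-0.19) than in AGS and with none past the size rule. TOP2A, topoisomerase II alpha, was at 42.8 FPKM against 25.2 (log2 -0.74) and UBE2C, a mitotic ubiquitin-conjugating enzyme, at 202 against 140 (log2 -0.52).

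Of 8 measured histone genes 6 were lower in MKN1 (median -0.48), with HIST1H2AC at 15.8 FPKM against 7.86. WNT targets (median 0.28), proteases and their inhibitors (0.29), autophagy and lysosome genes (0.26) and cholesterol synthesis genes (0.22) were high. Among lysosome and autophagy genes, ULK1, a kinase that starts autophagy, was at 17.5 FPKM against 38.3 (log2 1.08) and SQSTM1, an autophagy receptor, at 753 against 1220 (log2 0.70). YAP and TEAD targets (median -0.08) and heat shock genes (-0.09) lay low. Ribosomal protein genes (0.01) and MYC targets (0.02) lay low relative to random lists, with medians just above 0 that turn to -0.09 and -0.08 after centring. Interferon genes had a median of 0.21 at percentile 94.1, with 20 of 24 above 0, and S phase genes a median of 0.04 that turns to -0.05 after centring. In lists that stayed within the random range, single members differed by more than 2-fold: IL11, an interleukin 6 family cytokine, was at 80.4 FPKM against 25.2 (log2 -1.64), CDH2, N-cadherin, at 22.1 against 7.46 (log2 -1.45), LOXL2, a lysyl oxidase, at 133 against 41.5 (log2 -1.66), and ITGA5, integrin alpha 5, at 72.5 against 150.5 (log2 1.04). CDKN1A, the cell cycle inhibitor p21, was at 35.7 FPKM with siScramble and higher with siHOXB9 (log2 1.05).

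The largest positive differences among protein-coding genes with at least 5 FPKM in either library of MKN1 were those of ZNF28 (1.52 FPKM against 31.0, log2 3.67), BRD2, PHF1, ZHX3, HMGA2, RGS12, NAV3, PDSS2, ZNF778 and CMTM1. BRD2, a bromodomain protein, was at 0.429 FPKM against 13.4, HMGA2, an architectural chromatin protein, at 3.91 against 22.8, and PDSS2, an enzyme of coenzyme Q synthesis, at 5.06 against 22.4. The largest negative differences were those of ZNRD1, S100A6, EXOC6, GTF2IRD2B, MRAS, SET, ZNF595, HIST1H2BJ, GLO1 and CMPK1. S100A6, a calcium-binding protein, was at 748 FPKM against 97.0 (log2 -2.94), EXOC6, an exocyst subunit, at 38.9 against 4.78 (log2 -2.79), MRAS, a RAS-related GTPase, at 17.8 against 2.64 (log2 -2.37), and CMPK1, a nucleotide kinase, at 54.4 against 15.7 (log2 -1.73). ZNF28, BRD2, PHF1, ZHX3, HMGA2, ZNF778, CMTM1, ZNRD1 and S100A6 share exon sequence with another annotated gene, and ZNRD1, BRD2 and PHF1 lie in the MHC region.

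By the size rule, 276 genes were higher and 255 lower in MKN1 with siHOXB9 among 13122 genes, so 52.0% of the differences were upward. After centring on the median gene the split was 203 higher and 314 lower (39.3% upward), and with each library rescaled to the same total it was 280 and 315 (47.1%). Of 39 lists with at least 5 measured members, 12 stood apart from matched random lists, 5 high and 7 low, where 1.95 would be expected by chance. With a filter of 5 FPKM, WNT and YAP targets no longer stood apart while interferon genes (percentile 98.7), unfolded protein response genes (1.2) and proteasome subunits (97.8) did. That filter left 4 histone genes, too few to place among random lists. By the mean, WNT, YAP, cholesterol, heat shock and protease lists no longer stood apart and S phase genes did (percentile 1.63), and with unmatched random lists WNT, MYC, cholesterol and protease lists no longer did and gastric markers did (98.2). WNT, cholesterol, protease, ribosomal protein and lysosome genes no longer stood apart among protein-coding genes that share no exon, while S phase genes (0.46) and apoptosis regulators (99.98) did.

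The 2 lines together show which differences were repeated. Cyclin A2 (CCNA2), the S100 protein S100A6, the histone chaperone SET, the chromatin protein DEK, the replication licensing inhibitor geminin (GMNN), the methylglyoxal-detoxifying enzyme GLO1 and the corepressor LCOR were lower with siHOXB9 in both lines. S100A6 was at 1940 FPKM against 603 in AGS (log2 -1.69) and -2.94 in MKN1, CCNA2 at 36.2 against 12.5 in AGS (log2 -1.47) and 37.6 against 10.8 in MKN1 (log2 -1.70), and SET at 321 against 151 in AGS (log2 -1.09) and 443 against 106 in MKN1 (log2 -2.05). DEK was at log2 -1.28 and -1.01, GMNN at -1.01 and -1.61, GLO1 at -1.01 and -1.91 and LCOR at -2.04 and -1.38 in AGS and MKN1. HAUS4, a subunit of the augmin complex of the spindle, LSM3, an RNA processing factor, and the readthrough gene GPR75-ASB3 complete the 10 negative differences that rank first by the smaller of the 2 line changes, among protein-coding genes with at least 5 FPKM in a library of each line. TSGA10 (log2 -2.03 and -2.48) and ZNRD1 (log2 -1.61 and -2.96), which stayed under that level in a line, were also lower in both. Among the 10 positive ones by the same rule were HMOX1 (log2 1.62 and 1.67), ZHX3, a zinc finger and homeobox protein (2.03 and 2.69), CYP27B1 (2.95 and 1.17), BRD2 (1.07 and 3.33), the amino acid transporter SLC38A7 (1.02 and 1.44), the cyclin-dependent kinase inhibitor CDKN2B (1.09 and 0.87) and OSTM1, a partner of a lysosomal chloride transporter (0.95 and 0.93). PBXIP1, C7orf43 and TMEM164 complete these. S100A6, CCNA2, HAUS4, LSM3, GPR75-ASB3, TSGA10, ZNRD1, ZHX3, CYP27B1, BRD2 and C7orf43 share exon sequence with another annotated gene.

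Among 11547 genes measured in both lines, 24 were lower and 21 higher by the size rule in both, where independent lists would share 2.86 and 1.59, and 29 passed it in opposite directions, where 4.49 would be expected. Among protein-coding genes that share no exon, 5 were lower, 3 higher and 1 opposite, where 0.689, 0.333 and 1.02 would be expected, so the excess of opposite changes was not seen there. Across genes, Pearson's r between the changes of the lines was 0.131 and Spearman's rho 0.200. Pearson's r was 0.0567 with a pseudocount of 0.1 FPKM and 0.212 among protein-coding genes that share no exon, and rho was 0.120 without a filter on low values. In the limma fit over both lines, with the line as a block and 1 residual degree of freedom, no gene rose and 1 fell among 13758 at an adjusted p under 0.05, while 980 genes had an unadjusted p under 0.05, where 688 would be expected by chance. The gene that fell, RP11-192N10.2, named here after its values were seen, is known only by a clone name. It was at 10.6 FPKM in AGS and 6.51 FPKM in MKN1 with siScramble and listed at 0 in both siHOXB9 libraries (adjusted p = 0.0358). RP11-192N10.2 is thus among the 480 rows at 0 in a library and at 5 FPKM or more in another. For this gene the placement of reads was not told apart from a change in expression. HMOX1 (log2 1.64, SE 0.170), ZHX3 (log2 2.36) and TSGA10 (log2 -2.26) had an adjusted p of 0.0557, CCNA2 (log2 -1.58) of 0.0884 and S100A6 (log2 -2.31) of 0.104, each with its direction in 2 of 2 lines. Such agreement adds no support, because the residual of the fit is the disagreement of the lines and small p-values require it. HMOX1, ZHX3, CCNA2 and S100A6 passed when genes were kept only at 5 FPKM or more in 2 libraries, with adjusted p from 0.0170 for ZHX3 to 0.0285 for CCNA2. With a pseudocount of 0.1 FPKM, with rescaling and with quantile normalization 0 genes passed limma, at 834, 1093 and 1077 genes with an unadjusted p under 0.05. In simulated data the fit recovered 0 of 200 genes changed by 1 on the log2 scale and 161 of 200 changed by 2, with 7 false calls.

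**Figure D4:**
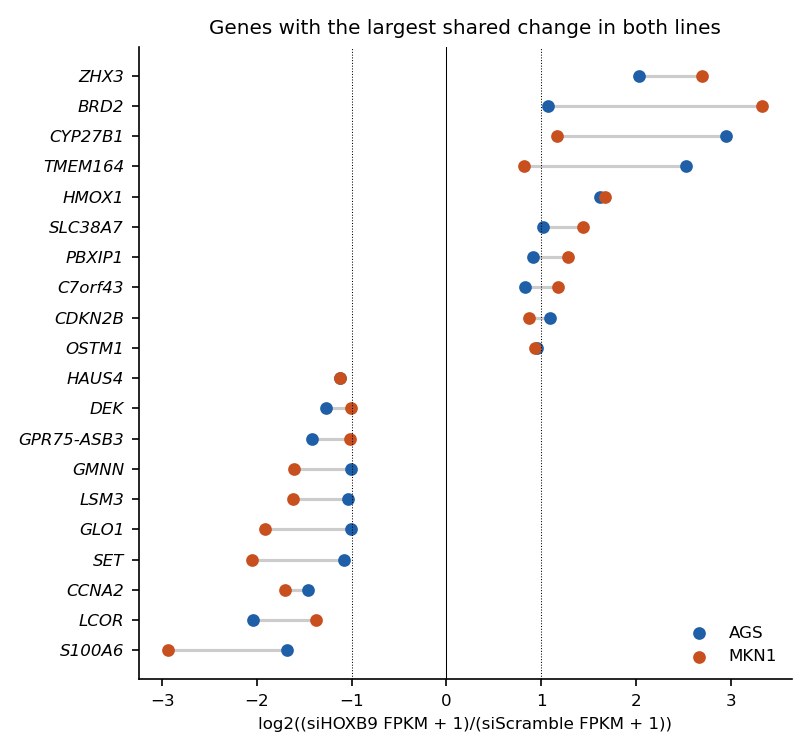
Log2 change (siHOXB9 against siScramble, 1 FPKM added) in AGS and in MKN1 of the 20 protein-coding genes that rank first by the smaller of their 2 line changes in the same direction, 10 lower and 10 higher, among those with at least 5 FPKM in a library of each line, 1 point per line and gene. HMOX1 lies at 1.62 and 1.67, and S100A6 at -1.69 and -2.94.

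Tested as groups over both lines with camera at its preset correlation of 0.01, 7 of 40 lists changed. G2M genes (adjusted p = 1.42e-20, median log2 -0.50), S phase genes (1.34e-08, -0.32), integrated stress response genes (0.000717, -0.20), ribosomal protein genes (0.00285, -0.10) and MYC targets (0.00695, -0.12) fell, and interferon genes (3.52e-10, 0.42) and autophagy and lysosome genes (0.00136, 0.19) rose. In MKN1 alone, integrated stress response genes had a median of 0.04, with 17 of 29 above 0. S phase genes (0.04), MYC targets (0.02) and ribosomal protein genes (0.01) also had medians above 0 there. The negative medians of these lists over both lines thus came from AGS on the uncentred scale, on which the median MKN1 gene changed by 0.098. Relative to matched random lists, ribosomal protein genes (percentile 0.01) and MYC targets (1.11) lay low in MKN1 as well. S phase (9.9) and integrated stress response genes (13) lay within the random range there. None of the 7 calls held with an estimated correlation (adjusted p = 0.993 with an estimated correlation for each). With fry, which tests whether the genes of a list move on balance one way, no list passed either (smallest adjusted p 0.401). Both tests rest on the 1 residual degree of freedom of the fit. Even the G2M list had an unadjusted p of 0.337 by camera with its estimated correlation (0.92). These tests could hardly pass any list, so their failure does not decide. The p-values at the preset correlation hold only if genes of a list vary nearly independently. No member of any list passed over all genes. Adjusted over the list alone, 1 member passed in each of 5 lists: S phase, TGF-beta targets, unfolded protein response, NRF2 targets and histones. The other 33 lists did not pass at the preset correlation. For p53 targets the median (0.01) lay above 0 while the test pointed down.

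The group medians of the lines differed in size or sign, which was described against random lists and not tested with replicates. The median difference between the AGS and the MKN1 change was 1.42 for mitochondrially encoded genes and 0.28 for interferon genes (percentiles 100 and 99.99), and -0.95 for integrated stress response genes, -0.59 for S phase genes and -0.58 for G2M genes (percentile 0 for each). For NRF2 targets it was -0.45 (percentile 0.16).

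HOX genes and secreted factors linked to HOXB9 were listed as groups of interest. Of 7 HOX genes measured in AGS, 5 were higher and 2 lower with siHOXB9 (median 0.26, percentile 96.1), and of 16 in MKN1, 7 were higher and 9 lower (median -0.04). With a pseudocount of 0.1 FPKM the HOX list stood apart in AGS (percentile 97.6), as it did against unmatched random lists, while by the mean it lay at percentile 66.2. No HOX gene of the list passed the size rule in either line, and with a pseudocount of 0.1 FPKM 1 was lower in AGS and 1 was higher and 1 lower in MKN1. In AGS, HOXB6 was at 18.8 FPKM against 20.1, HOXB3 at 8.94 against 11.7, HOXB5 at 3.86 against 5.01, HOXB13 at 0.983 against 1.37, HOXC6 at 2.28 against 3.06, HOXC13 at 5.26 against 4.26 and HOXC5 at 2.38 against 0.843. In MKN1, HOXA10 was at 8.70 FPKM against 14.0 (log2 0.63) and HOXB13 at 0.758 against 2.14 (log2 0.84), and the remaining 14 genes lay between -0.56 (HOXA6) and 0.36 (HOXC11). Of the secreted factors, VEGFA, the vascular growth factor, was at 60.4 FPKM against 53.3 in AGS and 59.6 against 66.4 in MKN1, TGFB1 at 91.8 against 74.1 and 87.2 against 81.2, TGFA at 6.18 against 7.61 and 2.30 against 4.94, and HBEGF at 5.13 against 3.89 and 5.97 against 5.17. In MKN1, IL6 was at 16.6 FPKM against 12.4, FGF2 at 16.6 against 17.0, TGFB2 at 16.04 against 16.98, NRG1 at 3.62 against 3.57, IL8 at 3.43 against 4.23, EREG at 1.55 against 2.14 and AREG at 0.368 against 1.06. The 11 factors measured in MKN1 had a median of 0.08. Both lists failed the camera test over both lines, with adjusted p of 0.735 for HOX genes and 0.828 for the factors.

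The last comparison described the 2 lines apart from the siRNA. AGS expressed gastric and intestinal epithelial genes, and MKN1 mesenchymal genes and a wider set of HOX genes. In AGS, LYZ, lysozyme, was at 2197 and 2163 FPKM against 2.01 in MKN1 siScramble (log2 difference MKN1 minus AGS -9.50, SE 0.165), and PLA2G2A, a secreted phospholipase, CTSE, the gastric protease cathepsin E, PAGE4, SPINT2, CST1, GATM, KRT19, FXYD3 and REG4 followed. In MKN1, IGFBP7, a secreted binding protein, was at 819 and 937 FPKM against 1.18 and 0.959 (log2 8.73, SE 0.184), followed by BASP1, CDKN2A, which encodes the cell cycle inhibitor p16, KRT7, KRT81, EEF1A2, SLC38A5, WISP2, PMEPA1 and GAL. All 20 of these genes had adjusted p between 4.85e-07 and 7.7e-07. Of 12 gastric markers 11 were higher in AGS and 1 in MKN1, all 10 intestinal markers were higher in AGS, and 18 of 23 epithelial junction genes were higher in AGS and 1 in MKN1. Of 24 mesenchymal genes 21 were higher in MKN1 and 1 in AGS, of 16 HOX genes 11 were higher in MKN1 and 3 in AGS, and of 38 interferon genes 29 were higher in AGS and 3 in MKN1. In the limma fit with the siRNA as a block, 2229 genes were higher in MKN1 and 2880 in AGS at an adjusted p under 0.05 and a difference of at least 2-fold. Each line has 2 libraries, which differ in their siRNA, and without a filter on low values the counts were 1271 and 1479.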

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

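The differences between the lines in this part were picked because the single libraries of the 2 lines went opposite ways, and none of them was tested, since each line has 1 library per group. Mitochondrially encoded genes had a median log2 change of 0.78 in AGS, with 13 of 13 above 0, and of -0.52 in MKN1, with 13 of 13 below 0. NRF2 targets had a median of -0.24 in AGS and of 0.54 in MKN1, with HMOX1 higher in both lines, and in AGS they did not stand apart from random lists with a filter of 5 FPKM (percentile 7.63) or by the mean (percentile 22.7). CMTM1, which shares exon sequence with another gene, was at log2 -2.57 in AGS and 1.86 in MKN1. SVIL, which encodes the actin-binding protein supervillin and also shares exon sequence, was at log2 2.81 in AGS and -1.56 in MKN1.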

How the results depend on the processing

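The restriction to protein-coding genes that share no exon and the centring of gene lists were chosen after seeing the data. HOXB9 was lower with siHOXB9 in both lines under every setting run. Rescaled to a common total, it was at 19.8 FPKM against 5.72 in AGS and 1.45 against 0.264 in MKN1, with log2 changes of -1.63 and -0.96, and with a pseudocount of 0.1 FPKM the changes were -1.86 and -1.96. The counts by the size rule followed the setting, as its construction implies. With a pseudocount of 0.1 FPKM, 452 genes were higher and 585 lower in AGS, 570 and 455 in MKN1, and 43 higher, 56 lower and 65 opposite in both lines. With a filter of 5 FPKM these were 101 and 155, 128 and 129, and 10 higher, 16 lower and 11 opposite, and with a size rule of 1.5-fold 747 and 1109, 1045 and 707, and 95, 132 and 103. Among protein-coding genes that share no exon they were 57 and 80, 77 and 70, and 3 higher, 5 lower and 1 opposite, where 0.333, 0.689 and 1.02 would be expected. Rescaling and centring kept the counts within 1.5 times. In the limma fit over both lines, 4 genes rose and 4 fell with a filter of 5 FPKM, which tests 10389 genes, and 3 rose and 4 fell with the robust option. With a pseudocount of 0.1, no filter, rescaling, quantile normalization or no shared exon, 0 rose and 0 fell, at 834, 879, 1093, 1077 and 434 genes with an unadjusted p under 0.05. Without the line as a block 0 fell, with 28 genes at an unadjusted p under 0.05, and the SE of HOXB9 went from 0.268 to 1.41, because the difference between the lines then enters the error. The line difference gave 1271 and 1479 genes without a filter on low values. With the estimated correlation 0 lists passed camera, and 0 passed fry, both resting on 1 residual degree of freedom and so unable to decide. Both a pseudocount of 0.1 and a filter of 5 FPKM gave the same 7 lists with camera at the preset correlation. Of 17 lists apart in AGS, 12 to 17 still stood apart on the same side over 5 settings (centring, which moves a list and its random lists alike, is not counted), and of 12 in MKN1, 7 to 12 did, and none went to the other side of its random lists. Of 80 changes of named genes, 80 kept their direction with the other pseudocount, rescaling and centring. A pseudocount cannot turn a direction, and rescaling and centring moved these changes by at most 0.264 and 0.098 on the log2 scale. Of 74 past the size rule, 70 stayed past it with rescaling and 71 with centring. The smaller pseudocount, which can only enlarge a change, moved them by up to 3.31. Causes other than those stated were not tested. MKN1 HOXB9 rests on an estimated 5.38 fragments with siHOXB9, and genes under 1 FPKM rest on few fragments.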

Other observations

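Some further single genes differed in these libraries. CANX, the endoplasmic reticulum chaperone calnexin, was lower with siHOXB9 in both lines, at 330.0 FPKM against 191 in AGS (log2 -0.79) and 427 against 153 in MKN1 (log2 -1.48), while the unfolded protein response list to which it belongs had medians of -0.01 and 0.03. CANX shares exon sequence with another annotated gene. Of the stem cell list, which stood apart in neither line (percentiles 94.7 in AGS and 95.4 in MKN1), the aldehyde dehydrogenase gene ALDH1A1 was at 5.38 FPKM against 16.3 in AGS (log2 1.44) and another, ALDH1A3, at 1.28 against 4.03 in MKN1 (log2 1.14). In AGS, KRT20, a keratin of the intestinal marker list, was at 0.364 FPKM against 2.71 (log2 1.44), INSIG1, which restrains sterol synthesis, at 114 against 51.9 (log2 -1.13), and S100A4, a calcium-binding protein, at 77.4 against 38.2. In MKN1 the TGF-beta targets PMEPA1 (log2 0.84) and SMAD7 (20.6 against 33.3, log2 0.67) were higher, and the list had a median of 0.16 at percentile 83.6.

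Markers of other cell types were also measured. Of 28 marker genes of T and B cells, myeloid cells and erythroid cells, 3 reached 1 FPKM in AGS siHOXB9, namely LYZ, CD68 and CSF1R. The median change over all 28 was 0, which markers near 0 FPKM give by construction with 1 FPKM added. LYZ was at 2197 FPKM in AGS siScramble and 2163 in AGS siHOXB9. In MKN1 the list of fibroblast markers had a median of 0.13 at percentile 61.0, with 7 members measured, among them LUM at 3.93 FPKM against 6.90.

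Of the tests that follow, those on protein-coding genes alone, the test of the MHC region and the 3 tests on interferon genes were chosen after the result was seen, and the ranking of words and the tests on all features before. The words were found and then described on the same libraries.

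In both lines, genes with the 7-base word AAGTACA in the 3' UTR were lower with siHOXB9 than genes without it. Of all words of 7 bases it had the strongest negative association in AGS (t = -7.37, effect -0.09) and also in MKN1 (t = -17.0, effect -0.21), with 919 genes that carry it, and AGTACAA, shifted by 1 base, was next in both lines with 675 genes. In a single permutation of the AGS changes the lowest t was -3.78. Each word occurs once in HOXB9 mRNA, in the 3' UTR part of exon 2, at 48622183 to 48622189 and 48622182 to 48622188 on the reverse strand of chromosome 17 (GRCh38), while 13.8% of all words occur somewhere in this mRNA. In AGS the mean log2 change was -0.08 (SE 0.00421) in 6401 genes with neither word, -0.12 (SE 0.0119) in 866 genes with exactly 1 of the words and -0.17 (SE 0.0190) in 364 genes with both, and in MKN1 it was 0.14, -0.04 and -0.17. Unlike the t values and effects, these means are not adjusted for 3' UTR length, GC content or expression. Their SEs are taken across genes, which are not replicates. Of the 10 named genes lower in both lines 8 carry either word, and of the 10 higher in both lines 1 does. Of the genes with the largest differences in a single line, 1 of 9 lower and 2 of 10 higher genes in AGS carry either word, and 4 of 10 lower and 3 of 10 higher genes in MKN1. The G2M genes of AGS had a median of -0.78 among 10 members with either word and -0.76 among 42 members without, and S phase genes -0.79 among 4 members with and -0.54 among 36 without. In MKN1 the medians were -0.31 with and -0.15 without for G2M genes, and -0.27 and 0.09 for S phase genes. The interferon genes of AGS had a median of 0.56 with either word and 0.68 without.

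A candidate explanation for part of the genes lower in both lines is seed matches of the siRNA in 3' UTRs, by which an siRNA lowers transcripts other than its target: the word that ranked first in AGS had rank 1 in MKN1 as well. Among protein-coding genes, 7 of 13 genes lower in both lines carry it, against 12.7% of 9900 others (odds ratio 7.99, two-sided Fisher's exact p = 0.000468), and for genes higher in both lines the odds ratio was 0.974. The word was picked on the AGS changes that also define these genes, so this p is not an independent test. It was not adjusted for 3' UTR length either. The rank in MKN1 used the MKN1 changes, which did not pick the word. The same test on all features could not be read, since 54.2% of the features lower in both lines have a 3' UTR that could be searched, and for the same reason (54.2% with a searched transcript) GC content or transcript length bias cannot be told apart on all features. Among protein-coding genes, removing trends on GC content and transcript length left 76.9% of the count, 10 genes, 9 of them the same, which speaks against these trends as the whole cause. The siRNA sequence is not given, so the match to the siRNA itself was not tested, and the loss of HOXB9, or a microRNA with the same seed, stays open for these genes and for those without the word.

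Changes past 2 on the log2 scale in a line may partly come from how reads were placed. Protein-coding genes with such a change lie in the MHC region of chromosome 6, of which the reference holds several alternate copies, in 5 of 40 cases, against 17 of 11727 genes that changed by less than 1 (odds ratio 98.4, two-sided Fisher's exact p = 8.84e-09). In that region 106 of 176 protein-coding genes (60.2%), TAP1, PSMB8 and HSPA1A among them, were listed at 0 in all libraries, against 17.6% of genes elsewhere. For reads split between overlapping genes the odds ratio among protein-coding genes was 1.23 (Fisher's exact p = 0.532, 22 of 40 against 5858 of 11727), while over all features found in the annotation, pseudogenes included, it was 1.85 (Fisher's exact p = 0.013, 48 of 72 against 6493 of 12498). Only 61.5% of all features with such a change were found there, so this explanation cannot be told apart from a real change for the whole pattern, and a response of these genes to the loss of HOXB9, which was not tested, stays open too.

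For the interferon genes higher in AGS, the tables argue against the scaling of the libraries. A scale factor moves genes of like expression alike, while the central 95% of random lists matched on expression ended at 0.0657 and the interferon list had a median of 0.67. For immune or blood cells, 3 of 28 markers reached 1 FPKM in AGS siHOXB9, among them LYZ, which AGS itself expresses. The median change over all 28 was 0. With 1 FPKM added, markers near 0 FPKM change by about 0, so this median could not show a rise. Too few of the markers reached 1 FPKM for the test to decide. Fibroblast and endothelial markers, of which 3 of 3 and 1 of 1 measured in AGS were above 0, leave other cell types open. Cells given siScramble were transfected with a duplex as well, so a response common to both siRNAs is already in the control. A response particular to the siHOXB9 duplex could still raise these genes. In MKN1 the list lay at percentile 94.1, between the bounds set for and against such a response. With a filter of 5 FPKM, which left 11 members, the list lay at 98.7, past the bound set for the response. It lay at 89.3 without shared exons, 93.7 with unmatched lists and 96.5 by the mean. With 1 library per group this response cannot be told apart from an effect of HOXB9 loss. The loss of HOXB9 stays among the open explanations.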
